A study of Mus musculus with 2 samples.

How the data were processed

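Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 2 replicates of the hybrid mouse embryonic stem cell line F121-6. The labels describe a female line from a cross of 129 and castaneus (CAS) mice, grown on inactivated mouse embryonic fibroblast feeders. They do not say whether the replicates came from separate cultures, so p-values describe only these 2 libraries, whose differences may be technical. The permutation, shuffle and Fisher tests compare segments or windows of the genome, not libraries. The submitters' processing notes name Bowtie2, MACS2, SAMtools and bedtools, without versions or roles, and the mm10 genome build.

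The deposited table holds counts, as whole numbers with no visible normalization, for each of 43941 windows of 50 kb, with 1 column per allele and replicate (4 columns, 0 further per-sample columns). What is counted, how fragments were assigned to an allele and which windows were left out are not given in the sources used here. The values run from 0 to 18. Between the 2 alleles of a replicate they vary less than independent reads would: the variance was 0.327 (replicate 1) and 0.468 (replicate 2) of the binomial variance in windows with 4 or more counts. They are therefore treated as small counts of sites or intervals whose read depth is unknown. Confidence intervals cover counting error only and are wide for values of this kind. The table covers chromosomes 1 to 19, and the X chromosome was not analysed here, so the X inactivation centre list and the list of X-linked genes that escape inactivation gave no values. On the 50 kb grid between the first and the last window of each chromosome, 3978 of 47919 windows are not in the table.

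Windows were annotated with gene positions of RefSeq on GRCm38.p6, whose primary sequence is mm10. A window overlaps a gene if any base is shared, exons and introns were not separated, and coordinates are 1-based. The column totals were 44026 and 46128 counts (129 and CAS alleles) in replicate 1 and 59812 and 59995 in replicate 2.

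The test fixed before the data were examined was edgeR's quasi-likelihood test with TMM scaling, filterByExpr with a minimum count of 10 and a Benjamini-Hochberg adjusted p threshold of 0.05. It assumed read counts, and on counts this small the filter kept 40 windows. An SE printed with an edgeR log2 difference was derived from that difference and its F statistic. It does not measure the spread between the 2 replicates. Alternatives fixed at the same time were the replicate as a block, DESeq2 size factors, 1 library size for both alleles of a replicate, the DESeq2 Wald test, no filter, windows above the median signal, an adjusted p threshold of 0.1 and pairs of adjacent windows. Chosen after seeing the data were bins of 500 kb, 1 Mb and 2 Mb, and limma on the square root of the count plus 0.375 with each column centred on its mean. The 2 alleles of a replicate come from 1 library, so the replicate number pairs them. Deviations of the 2 alleles of a replicate from the allele means correlated at r = 0.244 across windows.

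These fits were tested on simulated data with the window means and column totals of the table and 200 altered windows. The altered windows were drawn from those above the median signal, so recovery in weaker windows was not measured. The spread in the simulation was set after seeing the data, at 1.1 sites per mean count, to give about as many windows with opposite differences as the table holds. edgeR without a filter recovered 0% of windows altered 4-fold and 28% of those altered 16-fold. Centred limma recovered 36% and 96.5%, with 2 and 8 false calls. Limma without centring made 2102 and 2111 false calls, and limma with the replicate block recovered 0% at either fold. A second simulation, chosen after seeing the data, added a window effect shared by the alleles of a replicate (SD 0.3 on the natural log scale), which gave a correlation of deviations of 0.241. There centred limma recovered 21% and 84%, and limma with the block again 0%. In 1 Mb bins, simulated without the shared effect, edgeR recovered 0% of 1.5-fold and 48% of 2-fold changes, with and without the block. This does not show what the block does where the alleles of a replicate are correlated.

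The 129 share is the 129 count over the count of both alleles. Genome-wide shares have exact Clopper-Pearson 95% intervals. The planned median log2 ratio per chromosome was 0 in both replicates on every chromosome but 8, because of ties, so summed shares were used instead, a choice made after seeing the data. Their 95% intervals come from 10000 bootstrap resamples of 5 Mb segments. A two-sided permutation test exchanged the 496 segments with 40 or more counts between chromosomes 100000 times. Log2 ratios per window used a pseudocount of 0.5. Gene lists fixed beforehand were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and against 10000 random lists matched on signal.

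Windows were named by a rule fixed before the data were examined. With no window past the planned test, it took the 10 windows per side with the largest mean log2 ratio, among the upper 75% by signal with both replicates in 1 direction. It added imprinted windows that pass, the 2 windows with the largest absolute log2 ratio in each other list, and the longest run of adjacent windows per side. Of the 20 windows taken by size, 1 is not reported here. The run was taken over windows in 1 direction, since none passed. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.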

Results

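To compare open chromatin between the 2 parental genomes of 1 cell, allele-resolved ATAC-seq counts were examined in F121-6, a hybrid embryonic stem cell line carrying 1 chromosome set from 129 and 1 from CAS mice. The series asks where alleles differ in replication timing, genome organization, expression and accessibility. The accessibility part used here holds 2 replicates of 1 group. Counts per 50 kb window averaged 1.00 (129) and 1.05 (CAS) in replicate 1 and 1.36 and 1.37 in replicate 2. Of the 43941 windows, 9524 (21.7%) were at 0 in all 4 columns. The values vary less than independent reads would and their read depth is unknown, so a difference of a few counts is small in absolute terms.

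The 2 genomes contributed nearly equal counts. The 129 share was 48.8% (95% Clopper-Pearson interval 48.5 to 49.2%) of 90154 counts in replicate 1. In replicate 2 it was 49.9% (49.6 to 50.2%) of 119807 counts.

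Whole chromosomes departed from this balance, in both directions. Chromosome 10 had the highest 129 share, 57.7% ± 2.97 (SD, n = 2), at 59.8% (bootstrap interval 58.5 to 61.3%) in replicate 1 and 55.6% (54.1 to 57.3%) in replicate 2. Chromosome 8 had the lowest, 43.1% ± 1.90 (SD, n = 2), with 44.5% (43.8 to 45.2%) and 41.8% (41.0 to 42.7%). Chromosome 18 (44.7% ± 0.174), chromosome 14 (45.5% ± 0.533) and chromosome 7 (46.3% ± 0.538) also favoured CAS, and chromosome 2 (53.0% ± 1.02) and chromosome 17 (52.2% ± 0.559) favoured 129 (SD, n = 2 each). On chromosome 8 all 26 segments of 5 Mb were on the CAS side in both replicates, as were all 24 on chromosome 14, and 25 of 27 segments of chromosome 10 were on the 129 side.

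Chromosome identity accounted for 55.8% of the variance of the log2 ratio among 496 segments (permutation test, p = 1e-05, the smallest that 100000 permutations can give). After Benjamini-Hochberg adjustment over 19 chromosomes, 8 stood apart in the same permutation test: chromosomes 2, 7, 8, 10, 14, 17, 18 and 19. The interval of chromosome 19 included 50% in replicate 1 (51.1%, 48.8 to 53.3%) and excluded it in replicate 2 (56.0%, 53.6 to 58.4%). Across the 19 chromosomes the shares of the replicates correlated with Pearson's r = 0.819 (permutation p = 5e-05) and Spearman's rho = 0.946 (permutation p = 1e-05). Without chromosomes 2 and 10, the 2 farthest from the median in replicate 1, r was 0.936. Neighbouring segments are not independent, and chromosomes share 2 libraries, so these p-values describe these libraries.

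**Figure D1:**
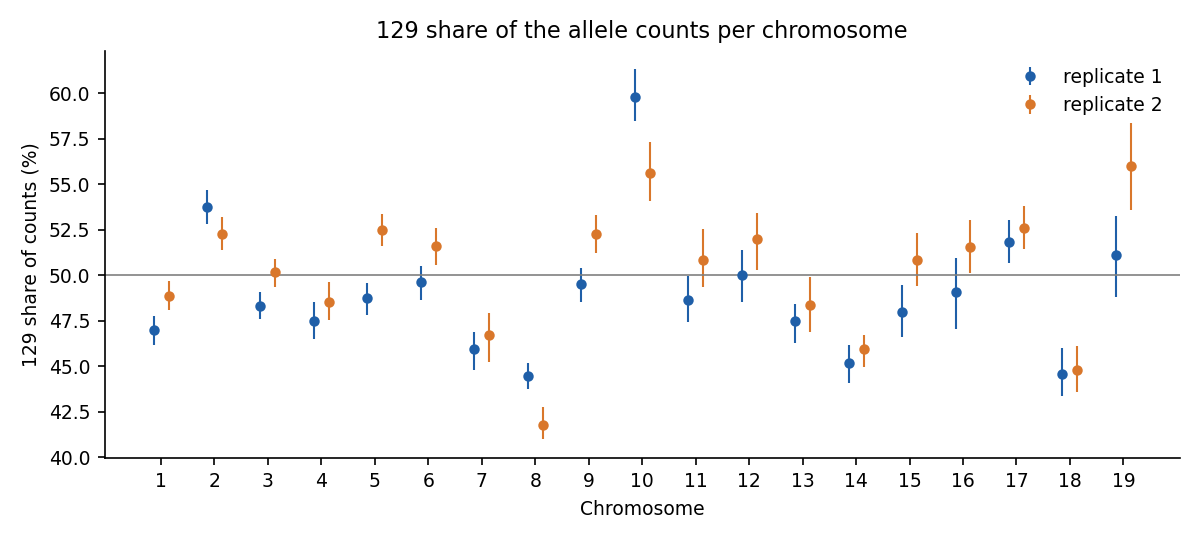
The 129 share of the allele counts (y axis, percent) on each chromosome (x axis) in replicate 1 (blue) and replicate 2 (orange), with 95% bootstrap intervals over 5 Mb segments. Chromosome 10 lies at 59.8% and 55.6%, and chromosome 8 at 44.5% and 41.8%.

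The excess of 129 on chromosome 10 was steepest at its start. The first 10 Mb had a 129 share of 75.6% in replicate 1 and 71.8% in replicate 2. Every other 10 Mb segment of the chromosome with 100 or more counts in replicate 1 lay between 53.6% and 64.5% in replicate 1 and between 50.6% and 65.2% in replicate 2. Beyond 20 Mb the chromosome still had a 129 share of 58.9% and 54.5%.

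**Figure D2:**
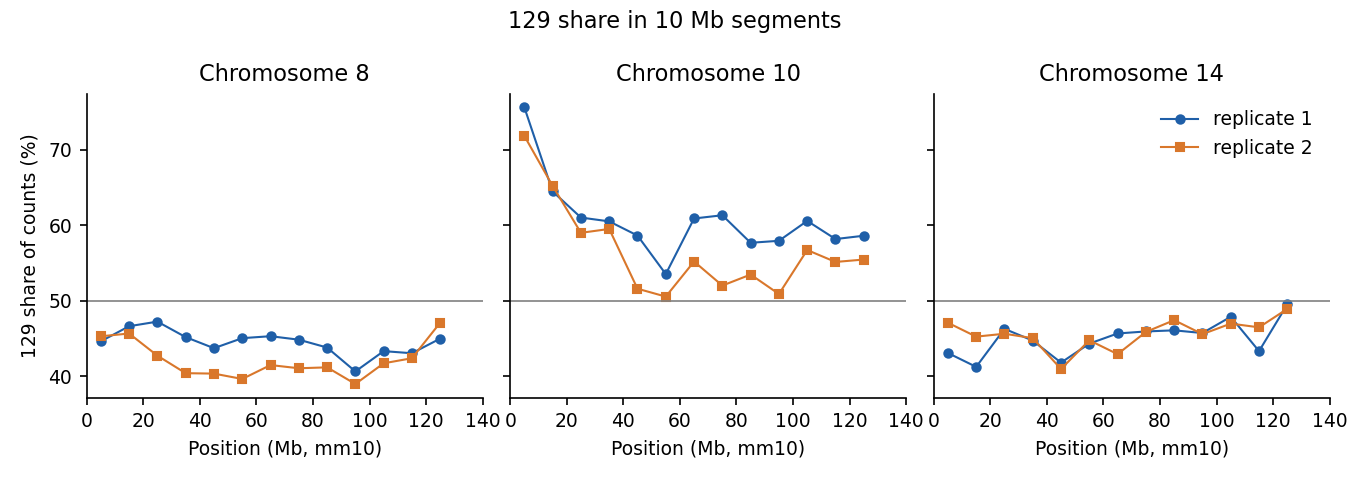
The 129 share of the allele counts (y axis, percent) in 10 Mb segments along chromosomes 8, 10 and 14 (x axis, Mb on mm10), in replicate 1 (blue circles) and replicate 2 (orange squares). The first segment of chromosome 10 stands at 75.6% and 71.8%, while all segments of chromosomes 8 and 14 lie below 50%.

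Among 1 Mb bins, those from 4 to 7 Mb of chromosome 10, around Esr1, the gene of oestrogen receptor alpha, favoured 129. They lie within the first 10 Mb, which favoured 129 throughout the values above. The bin from 7 to 8 Mb was alike (129 and CAS counts of 19 and 7, then 26 and 10) but did not pass (adjusted p = 0.056, edgeR with the replicate as a block). Bins were not tested against the level of the chromosome, so no difference local to Esr1 is shown. From 4 to 5 Mb (Mthfd1l, Akap12, Zbtb2, Esr1) the 129 and CAS counts were 32 and 9 in replicate 1 and 34 and 13 in replicate 2. From 5 to 6 Mb (Esr1, Syne1, Vip) they were 18 and 6, then 26 and 8, and from 6 to 7 Mb (Oprm1, the mu opioid receptor, and Ipcef1) 12 and 2, then 18 and 5. Further bins that passed on the 129 side lay at 77 to 78 Mb of chromosome 10 (Col18a1, Pofut2), at 149 to 150 Mb of chromosome 2 (Cst10, Syndig1) and at 106 to 107 Mb of chromosome 3, the cluster of the chitinase-like genes Chil3 and Chil4. There the log2 difference was 2.24 (SE 0.28, edgeR with the replicate as a block, adjusted p = 0.00208). A single 1 Mb bin passed on the CAS side: 91 to 92 Mb of chromosome 7, inside Dlg2, a synaptic scaffold gene, with 15 and 30 counts in replicate 1 and 28 and 80 in replicate 2. Its log2 difference was -1.33 (SE 0.14, adjusted p = 0.000128 in the same edgeR fit). Both SEs were derived from the F statistic and do not show the spread between the replicates.

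These 7 bins of 2095 passed only with the replicate as a block; edgeR without it called 0, with 50 bins at an unadjusted p under 0.05. The bin size was chosen after seeing the data, and without chromosome 10 the blocked fit called 3 bins.

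Single windows with counts from 1 genome only were found on both sides. The window beside B4galt6, a lactosylceramide synthase gene (chromosome 18, 20750001 to 20800000, 3597 bp from the gene), had 8 and 9 counts on 129 in replicates 1 and 2 and 0 on CAS in both. A window near Chil4 (chromosome 3, 106250001 to 106300000) had 4 and 11 on 129 and 0 on CAS. On chromosome 10, the window at 3950001 to 4000000, which overlaps Plekhg1 and the mitochondrial folate enzyme gene Mthfd1l, had 5 and 6 against 0. The windows near Bicc1 (70850001 to 70900000, 4 and 5 against 0) and Pofut2 (77200001 to 77250000, 3 and 4 against 0) lay on the same chromosome. Slc35c1, a GDP-fucose transporter gene (chromosome 2, 92450001 to 92500000), and Ap1m2 with Slc44a2 (chromosome 9, 21300001 to 21350000) each had 4 and 4 counts on 129 and 0 on CAS. Windows near Noct (chromosome 3, 51100001 to 51150000) and over 3 V segments on chromosome 6 (67850001 to 67900000) each had 3 and 4 on 129 and 0 on CAS.

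On the CAS side, the window over Spin1, a reader of histone methylation (chromosome 13, 51050001 to 51100000), had 7 and 4 counts on CAS and 0 on 129. A window over Map4k3, a kinase gene (chromosome 17, 80650001 to 80700000), had 6 and 8 on CAS against 0 and 1 on 129. The direction was opposite at 80800001 to 80850000, whose nearest gene is also Map4k3, with 9 and 11 on 129 against 3 and 5. The window near the vomeronasal receptor gene Vmn2r68 (chromosome 7, 85250001 to 85300000) had 6 and 14 on CAS against 0 and 2. A window over 3 V segments on chromosome 12 (113950001 to 114000000) had 7 and 7 on CAS against 0 and 1. Windows near Rpp21 (chromosome 17, 36200001 to 36250000) and 315980 bp from Usp24 on chromosome 4 (105950001 to 106000000) each had 4 and 4 on CAS, and Gm1966 (chromosome 7, 106600001 to 106650000) had 3 and 5, with 0 on 129. The last windows were near Slitrk5 (chromosome 14, 111550001 to 111600000, 2 and 6), near Bnc2 (chromosome 4, 84750001 to 84800000, 4 and 3) and 376808 bp from Anxa10 on chromosome 8 (62500001 to 62550000, 3 and 4), again with 0 on 129.

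The planned edgeR test tested 40 windows and called 0, with 0 at an unadjusted p under 0.05, and the DESeq2 Wald test also called 0. Without a filter edgeR called 0 of 34417 windows, with 910 at an unadjusted p under 0.05. Of 333 pairs of adjacent windows that passed the filter, edgeR called 1, at 20700001 to 20800000 on chromosome 18 beside B4galt6, with a log2 difference of 2.12 (SE 0.33, adjusted p = 0.0152). Limma on centred square roots, chosen after seeing the data, called 69 windows higher on 129 and 65 higher on CAS. With the replicate as a block limma called 0 windows, in a fit that also recovered 0% of simulated changes, with or without a simulated effect shared by the alleles of a replicate. Of the 134 windows, 78 overlapped a coding gene, near the share over all windows (25395 of 43941). Chromosome 10 held 12 of the 134 on the 129 side and 3 on the CAS side.

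Direction was shared between replicates more often than not. At a difference of 3 or more counts in each replicate, 103 windows were higher on 129 in both, 119 were higher on CAS in both, and 18 were opposite. If replicates were independent and all windows alike in signal, 19.4 windows would share a direction at that difference. Windows with such a difference lay mostly at high signal, so 19.4 is not a fair reference. The 18 opposite windows, counted at the same difference, are the comparison to use. The longest run of adjacent windows with 129 higher in both replicates spanned 7 windows of chromosome 10 (66800001 to 67150000), over Reep3 and Jmjd1c, a histone demethylase gene of the JmjC family, with 27 and 18 counts (129 and CAS) in replicate 1 and 34 and 21 in replicate 2. The longest CAS run spanned 6 windows of chromosome 12 (114300001 to 114600000), with no coding gene and with V segments in it, and held 17 and 37, then 41 and 65.

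**Figure D3:**
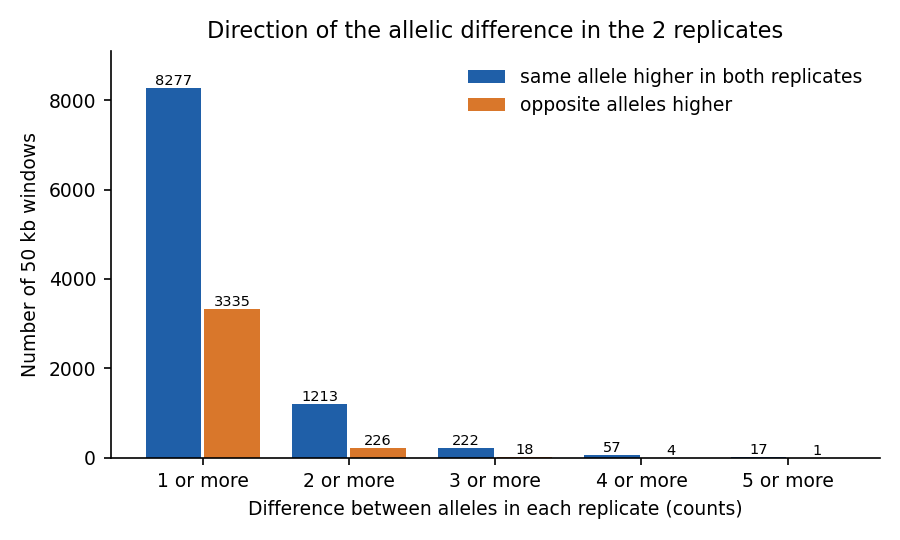
Number of 50 kb windows (y axis) whose alleles differ by at least the given number of counts in each replicate (x axis), with the same allele higher in both replicates (blue) or opposite alleles higher (orange). At 3 or more counts, 222 windows share a direction and 18 do not.

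Imprinted genes were split between the alleles. Of 27 paternally expressed imprinted genes with a count, 6 were higher on 129 and 3 higher on CAS in both replicates; of 25 maternally expressed genes, 2 and 2. Plagl1, a zinc finger gene on chromosome 10, had 6 counts on 129 and 2 on CAS in each replicate, and Slc38a4, an amino acid transporter gene, had 4 and 7, then 1 and 6. Grb10, an adaptor of growth factor receptors, had 8 and 4 in each replicate. A Usp29 window (chromosome 7, 6950001 to 7000000), with 5 and 1, then 5 and 2, passed centred limma adjusted over the list alone (adjusted p = 0.0136) and did not pass over all windows (adjusted p = 0.0619). In camera the paternally expressed list had an adjusted p of 0.992 and the maternally expressed list 0.818. Genes that share a window, such as Cd81 and Tssc4, are not independent. Windows are also shared between the lists, as by Airn (paternally expressed) and Igf2r (maternally expressed). The parent of origin of each allele was not used, so these values do not test imprinting.

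Pluripotency genes carried many counts on both alleles. Summed over its windows, Esrrb had 19 and 20 counts (129 and CAS) in replicate 1 and 22 and 28 in replicate 2, and Nanog had 9 and 7, then 11 and 8. Of 29 pluripotency genes, 7 were higher on 129 and 3 on CAS in both replicates (camera adjusted p = 0.867). The windows with the largest ratios held few counts: a window of Nr5a2 had 2 and 1 on CAS against 0 on 129, and a window of Sall4 had 1 and 2 against 0. Over all its windows Nr5a2 had 7 and 10 on 129 and 9 and 9 on CAS, and Sall4 had 1 and 0 on 129 and 1 and 2 on CAS. Replication timing and chromatin architecture genes included Ctcf, with 6 and 4 counts on 129 and 7 and 7 on CAS over 2 windows, 1 of which had 1 and 2 on CAS against 0. Hells had 5 and 7 on 129 and 3 and 3 on CAS over 2 windows, 1 of which had 3 and 5 against 1 and 2. Of these genes, 3 of 24 genes were higher on 129 and 7 on CAS (camera adjusted p = 0.780).

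The clustered protocadherin genes on chromosome 18, which give neurons distinct surface identities, were more often higher on CAS. All 57 had a count, in 16 shared windows, and 37 were higher on CAS in both replicates against 0 on 129. The mean log2 difference was -0.25, and camera gave p = 0.105 (adjusted p = 0.679; p = 0.224 with an estimated correlation). Its median of -0.29 lay at the 0.01 percentile of 10000 random lists matched on signal, which ignore that the windows are neighbours on 1 chromosome. The other 12 lists lay between the 15.45 and 89.6 percentiles. Centred limma adjusted over the list alone passed 3 windows and over all windows 0: the start of the Pcdha genes (36950001 to 37000000; 3 and 4 on CAS, 1 and 1 on 129), Pcdhb3 to Pcdhb7 (37300001 to 37350000; 3 and 2 against 0 and 1) and Pcdhb9 to Pcdhb14 (37400001 to 37450000; 2 and 3 against 0 and 1). Chromosome 18 as a whole favoured CAS, and after centring each chromosome, a step chosen after seeing the data, the mean was -0.13.

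No list passed camera. Housekeeping genes included Actb, with 3 and 2 counts on 129 and 6 and 4 on CAS, and Tbp, whose 2 windows summed to 3 and 5 on 129 and 2 and 4 on CAS (2 and 3 against 1 and 2 in the window with the larger ratio). Of 17 genes, 3 were higher on each allele in both replicates (adjusted p = 0.971). Lineage genes silent in stem cells included Cdx2 (4 and 2 on 129, 3 and 0 on CAS) and Gata6 (1 and 0 on 129, 2 and 1 on CAS), with 4 higher on 129 and 1 on CAS of 23 (adjusted p = 0.780). The fibroblast markers Cd44 and Thy1, which feeder cells express, each had a window with 1 and 1 on 129 and 0 on CAS; Cd44 as a whole had 2 and 4 on 129 and 1 and 2 on CAS. Of 26 markers with a count 4 were higher on 129 and 2 on CAS (adjusted p = 0.780). Hox clusters had 5 of 27 genes with a count higher on 129 and 0 on CAS (adjusted p = 0.780). Only 8 Hox windows held a count, so genes that share a window are not independent. A window shared by Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13 had 3 and 2 on 129 against 2 and 0, and a Hoxa window 1 and 1 against 1 and 0. Histone genes, 17 with a count in 7 windows, had 3 higher on 129 and 0 on CAS (adjusted p = 0.679). A window shared by H2ac13, H2bc13 and H2bc14 had 7 and 8 against 6 and 6, and a window at H2ac6 had 3 and 3 against 3 and 2.

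Receptor and zinc finger families were split between the alleles. Of 588 olfactory receptor genes with a count, which shared 307 windows, 54 were higher on 129 and 61 on CAS (adjusted p = 0.849). Olfr19 had 2 and 2 on 129 against 0 and Olfr175 2 and 2 on CAS against 0. The Olfr875 window on chromosome 9 (37750001 to 37800000; 4 and 5 against 1 and 1) passed centred limma over all windows (adjusted p = 0.0419), the single called window in any fixed list. Vomeronasal receptor genes had 23 higher on 129 and 11 on CAS of 144 (adjusted p = 0.881), with windows of Vmn1r89 and Vmn2r58 each at 1 and 3 on 129 against 0. Zinc finger genes had 42 and 50 of 324 (adjusted p = 0.949), with a window of Zfp236 at 3 and 3 on CAS against 1 and 0, and a window of Zfp951 at 1 and 2 on 129 against 0. edgeR without a filter called 0 windows adjusted over the list alone in each of the 13 lists.

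Window by window the allelic difference was only partly shared. Across 34417 windows with a count, the log2 ratios of replicates 1 and 2 correlated at r = 0.267 (bootstrap interval 0.254 to 0.279) and rho = 0.260; windows are not independent replicates. The SD of the ratio between replicates fell from 1.12 in the tenth of windows with the lowest signal to 0.462 in the tenth with the highest, which held 144 of the 222 windows with a difference of 3 or more. Adjacent windows resembled each other weakly, at r = 0.0964 against a mean of 0.0384 and a highest value of 0.0555 in 1000 shuffles within chromosomes (p = 0.001, the smallest they can give). In replicate 1 alone r was 0.0603, against a shuffled mean of 0.0257, and in replicate 2 alone 0.0734, against 0.0274. With replicate 1 of a window set against replicate 2 of its neighbour r was 0.0533, against a shuffled mean of 0.0219 and a highest value of 0.0342. After centring each chromosome it was 0.0321, against a highest value of 0.0124; these shuffles across replicates were chosen after seeing the data.

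Replicates differed most where genes were few. With 1 Mb bins ordered by coding genes and cut into 4 groups of equal size, the group with 0 to 2 genes stood apart: replicate 2 held 2.11 times the counts of replicate 1 on the 129 allele and 2.00 times on the CAS allele. In the group with 11 to 67 genes the ratios were 1.02 and 0.974. The 129 share within these 2 groups was 47.7% and 49.2% in replicate 1, and 49.0% and 50.4% in replicate 2.

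**Figure D4:**
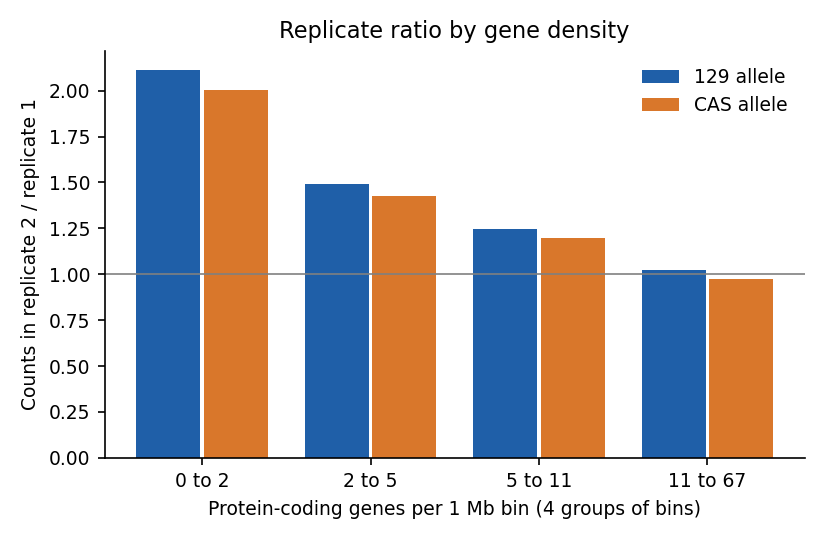
Ratio of the counts in replicate 2 to those in replicate 1 (y axis) for the 129 allele (blue) and the CAS allele (orange), in 4 groups of 1 Mb bins ordered by the number of protein-coding genes (x axis). The ratio is 2.11 and 2.00 in the gene-poorest group and 1.02 and 0.974 in the gene-richest.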

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

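The wider bins, the limma fits, centring by chromosome and the left-out chromosomes were chosen after seeing the data. The planned count of 0 windows was also 0 with the replicate block, DESeq2 size factors, a common library size, the DESeq2 Wald test, no filter, windows above the median signal and an adjusted p of 0.1. It was 1 for window pairs, and with the replicate block 4 for 500 kb bins, 7 for 1 Mb bins (3 without chromosome 10) and 8 for 2 Mb bins, against 0 in each of these 3 bin sizes without the block. Limma on square roots called 134, and 2795 without centring, of which 28 were shared; simulated data gave 2102 false calls without centring. Above the median signal the 129 share was 46.2% on chromosome 14, 45.6% on chromosome 18 and 47.0% on chromosome 7, and replicate agreement was 0.312. Clustering was 0.0784 without a filter, 0.119 above the median signal and 0.0603 to 0.0734 leaving out a replicate. Of 52 list alternatives that keep both replicates, 48 kept their side of the mean of all windows (-0.0132 in the planned setting) and 0 passed. The exceptions were housekeeping (-0.0038) and pluripotency (-0.0145) windows within 50 kb, and paternally expressed (0.0086) and zinc finger genes (0.0094) after centring each chromosome. Leaving out a replicate changed the sign of 4 list means: pluripotency (-0.0239) and paternally expressed genes (0.018) without replicate 2, and maternally expressed (-0.001) and housekeeping genes (0.0018) without replicate 1. For these the cause was not tested. The block changed no list call. Not run: calls without a replicate (no residual degrees of freedom), the settings for normalized values, and the X against autosomes; "autosomes only" equals the values above. Counts near 1 per window limit single-window tests: centred limma recovered 36% of 4-fold changes simulated in windows above the median signal.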

Other observations

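Every test in this part was chosen after its result was seen, except the comparison of gene-poor and gene-rich bins with deeper or more permissive calling. Summed over alleles and replicates, which gives the larger replicate 2 more weight, the windows with the highest totals of the table included one inside Esrrb, a nuclear receptor gene of the pluripotency network (chromosome 12, 86450001 to 86500000, 49 counts). Windows at Jade1, at Manba with Nfkb1, and at Myo10 had 47 each, and the order of these windows differed between replicates. Of the 10 windows with the highest totals, 1 held a gene of the pluripotency list. Windows of pluripotency genes averaged 7.85 counts over both alleles in replicate 1 and 9.44 in replicate 2, against 2.05 and 2.73 over all windows, and 0% of them were at 0. Their mean lay above all 10000 random lists of windows of the same size. Windows of housekeeping genes (6.48 and 5.44), histone clusters (8.75 and 8.88) and zinc finger genes (3.76 and 3.80) were also above all random lists. Every list window overlaps a gene, while the random lists were matched on size. Mean 129 counts per window were 0.58 in the gene-poorest and 1.35 in the gene-richest group of 1 Mb bins in replicate 1. In replicate 2 they were 1.23 and 1.39. A high percentile therefore does not set a list apart from gene windows in general.

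Hox and receptor clusters held fewer counts. Only counts assigned to an allele are seen, by a rule not given, so a low level need not mean less accessible chromatin. Hox cluster windows averaged 1.54 and 0.923 counts, at the 3.03 percentile of random lists, and 38.5% were at 0. Vomeronasal receptor windows averaged 0.872 and 1.59, and olfactory receptor windows 1.26 and 2.19, both below all random lists. Lineage genes silent in stem cells were not low, at 4.25 and 3.71 (percentile 99.7). Replication timing and chromatin architecture genes (3.96 and 4.33) were at percentile 99.98, protocadherins at 97.7, and the paternally and maternally expressed imprinted genes at 96.1 and 83.8. Fibroblast markers, which the feeder cells would bring, were at 2.72 and 3.13 (percentile 91.4). Random lists ignore that windows of a cluster are neighbours.

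The 129 share differed between chromosomes, with chromosome 10 high and chromosomes 8, 14 and 18 low. A uniform mapping preference for 1 genome would push all chromosomes 1 way, but at least 3 chromosomes had intervals that excluded 50% in both replicates on each side. A mapping preference that differs between regions was not tested and stays open. A few strong windows are argued against by 78.95% or more of the 5 Mb segments lying on the chromosome's side on chromosomes 8, 10 and 18. A gain or loss of chromosome 10 as a whole in part of the cells would give no local peak, and cannot alone account for a start that exceeded every other segment by 6.63 percentage points or more in both replicates. For chromosomes 8 and 14 that remains a candidate explanation, which the evenness of their profiles cannot decide. Their profiles were not level, with an SD between 10 Mb segments of at most 2.46 percentage points. On the 16 other chromosomes it was 1.45 to 3.92 in replicate 1 and 1.42 to 4.19 in replicate 2. On chromosome 10 it was 5.17 and 6.13. Chromosomes 8 and 14 lay within the range of the other chromosomes, so evenness does not set them apart. A regulatory difference between the strains spread over the chromosome was not tested and stays open beside a gain or loss.

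Windows with a difference of 3 or more counts in both replicates could come from gene clusters that vary in copy number or sequence between strains. As the whole cause, olfactory receptor, vomeronasal receptor and V segment clusters are argued against, because 4.5% of the 222 windows overlapped them. Only overlap was counted, so the window near Vmn2r68 fell outside. Other gene clusters were not counted and copy number was not measured, so the value leaves variation outside these families open. Inside V segment clusters windows with such a difference were frequent, 8 of 222 against 20 of 11398 other windows with enough counts (odds ratio 21.3, two-sided Fisher's exact test, p = 3.5e-08). Variation between strains stays open there: 7 of the 8 lie on chromosome 12 and 1 on chromosome 6, so neighbouring windows are counted as if independent. The other windows were also not matched on signal, and 144 of the 222 lie in the tenth of windows with the highest signal. A V segment window of chromosome 12 (114400001 to 114450000, 45 counts) is among the 10 highest of the table. The odds ratio therefore does not separate V segments from high signal. A difference in regulation between the alleles was not tested.

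Replicate 2 gained counts unevenly along the genome, in a comparison of 1 library with 1 library. A single scaling factor would give 1 ratio everywhere, but the ratio in bins with 0 to 2 genes was at least 1.94 times that in bins with 11 to 67 genes (lower bound of the 95% bootstrap interval over 5 Mb segments, smaller of the 2 alleles). Deeper sequencing or more permissive calling of weak sites would add counts where genes are few. The ratio of replicate 2 to replicate 1 was 2.06 times as high in the gene-poor bins on either allele, which is consistent with that explanation. The read depth is unknown, and a difference in the cells between the replicates was not tested.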
